A study of Homo sapiens with 6 samples.

How the data were processed

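Poly-A RNA of Jurkat cells treated for 24 h with H3B-8800 or DMSO was sequenced as paired reads of 300 bases on an Illumina NextSeq instrument, per the labels' protocols. The sample labels describe a strand-specific dUTP library, whereas the series' design text describes an unstranded one with other read lengths, and how strand was used in counting is not given in the sources used here. The values of overlapping and antisense genes are therefore uncertain, and so are those of genes with near-identical copies. The submitters' processing notes name bcl2fastq, TopHat, HTSeq, edgeR and the hg19 build, without roles or versions.

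The authors deposited 1 table with CPM values of 6 libraries. It also holds the authors' log2 fold change and mean log2 CPM, a likelihood-ratio score, and a p-value with its adjusted p-value, per the file headers. The authors' flags of a rise or fall follow the sign of the fold change. The table was found to be a selection. All 2920 rows are protein-coding, the highest adjusted p-value in the authors' deposited table is 0.0099, every risen gene has at least 50 CPM in H3B-8800 replicate 1, and every fallen gene has at least 50.1 CPM in DMSO replicate 1. The ratio of adjusted to raw p-value in the authors' deposited table gives about 15200 genes tested by the authors, with the last listed gene at 45.9% of the ranks. Genes outside the table are not analysed here.

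The deposited CPM values are reads divided by the whole library size, with no further factor. Library sizes at which all 2920 values of a library are whole reads to within 0.01 read were found for each library, and ranged from 24250924 to 30642470 reads. The authors' log2 fold change differed from the log2 ratio of the mean CPM by at most 0.008. No sample column was left unused.

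The test planned before the data were examined assumed counts. As the table holds CPM, the fall-back written with that plan was used: limma 3.58.1 in R 4.3.3, with a trended empirical Bayes fit (eBayes) of log2(CPM + 1) on treatment over all 6 libraries, 2 groups of 3, two-sided, with Benjamini-Hochberg adjustment over the 2920 listed genes at 0.05. No filter on low values was needed, since every gene passed it. Gene lists fixed before the data were examined, 27 in all, were tested with camera at a preset correlation of 0.01 where at least 5 members were listed (17 lists, Benjamini-Hochberg over these), and again with an estimated correlation and with fry. Named genes followed a rule fixed beforehand: SF3B1; the 6 largest rises and 6 largest falls among genes past the test with a mean log2 CPM of at least 3 and groups that did not overlap; the member with the smallest p of each biological list, or the 2 smallest where the list passed camera; and the most abundant member of every other list. This gave 40 genes, of which one is not reported here. Further members named beside them as examples were chosen after their values were seen.

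The fit was tested on simulated data drawn for the 2920 genes with a dispersion of 0.003 and 200 changed genes. For this comparison limma found 74% of changes of 0.25 on the log2 scale and 100% of those of 0.5, 1 and 1.5, with 7 false calls (3.6% of calls). Most simulated genes were unchanged, whereas all real listed genes had been selected as changed on these libraries. The simulated rates therefore do not carry over to the real calls. Replicates of a group differed by more than counting noise in every pair (chi-square over degrees of freedom from 3.38 to 11.35), so none was counted as a duplicate. The first principal component held 93.2% of the variance and separated the groups.

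Alternatives covered the pseudocount (0.1 and 5), limma-voom on the whole reads, scaling factors computed on the listed genes, the replicate number as a block, each library left out, a stricter threshold, a minimum fold, the authors' own columns and other list tests. Intron number, GC content and length came from GENCODE 29 by gene identifier, which gave a transcript for 2893 listed genes (99.1%), taking the one with the longest coding sequence. That annotation is on another build, and coordinates are given as in the authors' table. Properties were computed with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and figures drawn with matplotlib 3.10.9.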

Results

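Messenger RNA of Jurkat cells, an established line from a human T cell acute lymphoblastic leukemia (T-ALL), was sequenced after 24 h with H3B-8800 or with its solvent DMSO. H3B-8800 is a small molecule that binds SF3B1, the largest subunit of the SF3b complex, which recognises the intron branch site during pre-mRNA splicing. Each of the 2 groups held 3 libraries. The DMSO libraries held 30642470, 29798115 and 26847459 reads and the H3B-8800 libraries 24250924, 25228855 and 25308596, as worked out from the steps between the deposited CPM values, which give a gene's share of its library's reads. Values were at hand for 2920 protein-coding genes, which the authors had already selected as changed between these same 6 libraries and as expressed at about 50 CPM or more. A library of this depth measured a gene at 50 CPM with a counting error of 2.55% to 2.87%, and the listed genes took between 41.5% and 42.5% of each library's reads. The labels do not say whether the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

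The comparison of H3B-8800 with DMSO asked which genes changed in level when the SF3b inhibitor was present. SF3B1 itself rose, from 574 ± 16.2 CPM in DMSO to 867 ± 13.3 CPM in H3B-8800 (SD, n = 3 each), a log2 fold change of 0.59 with a standard error of 0.04 (limma, adjusted p = 2.03e-08). SF3B1 (ENSG00000115524) lies on chromosome 2 from 198254508 to 198299815 on the minus strand in the hg19 build. The largest rise among the listed genes was that of ID3, an inhibitor of basic helix-loop-helix transcription factors, which went from 40.5 ± 2.99 to 116 ± 5.76 CPM (log2 fold change 1.49, standard error 0.06, limma adjusted p = 1.17e-10). The largest fall was that of CHML, a Rab escort protein gene, from 53.7 ± 6.21 to 14.2 ± 0.95 CPM (log2 fold change -1.84, standard error 0.08). CDC40, a second-step splicing factor, followed with a log2 fold change of -1.77, from 66.1 ± 3.42 to 18.7 ± 1.93 CPM.

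The other genes with the largest falls were C22orf39 (log2 fold change -1.65), IGLL1, a surrogate immunoglobulin light chain gene (-1.54), the G protein-coupled receptor GPR174 (-1.45) and SPNS3 (-1.44). The other genes with the largest rises were CPNE1, a calcium-dependent phospholipid-binding protein (0.89), C10orf12 (0.88), the interferon-inducible GTPase GBP1 (0.87), the cadherin CDH4 (0.84) and TRIM4 (0.83). ID3 (ENSG00000117318) lies on chromosome 1 from 23884409 to 23886285, CHML (ENSG00000203668) on chromosome 1 from 241792155 to 241799232, and CDC40 (ENSG00000168438) on chromosome 6 from 110501344 to 110575478, all in hg19. CHML overlaps OPN3 on the same strand and C22orf39 overlaps HIRA on the same strand and MRPL40 on the other in the gene annotation, so reads of these neighbours could be counted with them. Same-strand overlaps were also annotated for CPNE1 (with RBM12), TRIM4 (with OR2AE1), DDX46 (with C5orf24), BUB1B (with the read-through gene BUB1B-PAK6), CDH4 and RRM2, and overlaps on the other strand for further named genes, among them CDC40 (with METTL24) and FANCI (with POLG). C10orf12 had no match in that annotation.

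Of the 2920 listed genes, 1527 rose (52.3%) and 1393 fell (47.7%) in the limma fit at an adjusted p under 0.05. The genes that rose had a median log2 fold change of 0.28 and those that fell one of -0.32. A fall of at least 1 on the log2 scale was seen for 39 genes, and ID3 was the 1 gene with a rise of that size. The authors' deposited table gave 43 such falls and 1 such rise. In 2885 of the genes every H3B-8800 library lay on one side of every DMSO library, an arrangement that chance gives for 10% of genes. Because the authors chose the genes on these libraries, the counts are not independent evidence of change, and genes outside the list have no value here.

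**Figure D1:**
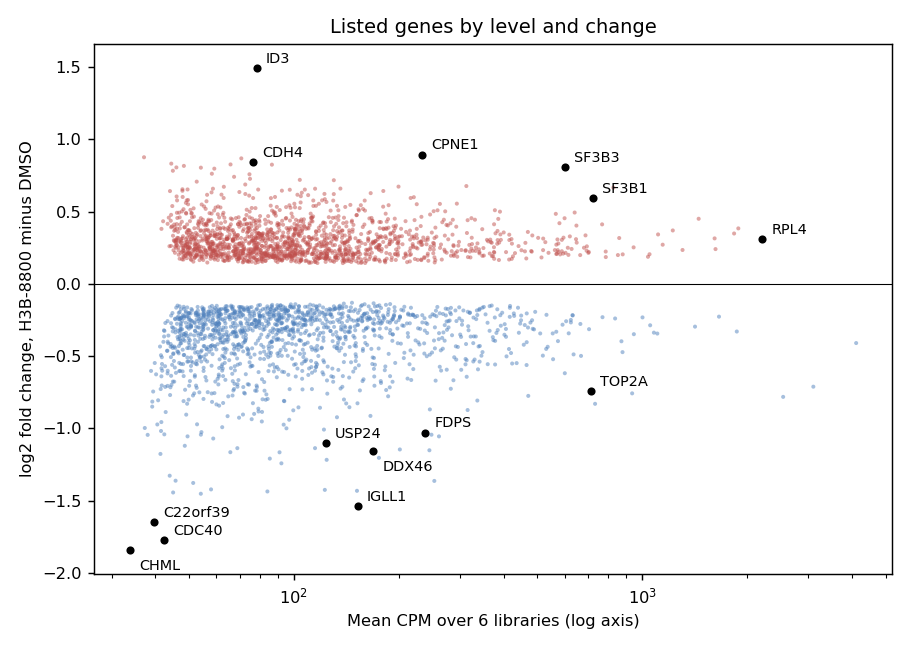
Each point is one of the 2920 listed genes, placed by its mean CPM over the 6 libraries (log axis) and its log2 fold change of H3B-8800 minus DMSO, with risen genes in red, fallen genes in blue and 14 genes labelled in black. ID3 stands alone above 1 at 1.49, while 39 genes lie at or below -1, down to CHML at -1.84.

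Genes of the machinery that H3B-8800 binds mostly rose. Of the 19 genes of the SF3b and U2 small nuclear ribonucleoprotein list, 16 were listed, of which 13 rose and 3 fell, with a median log2 fold change of 0.31 (camera adjusted p = 0.0394, and adjusted p = 0.518 with an estimated correlation). SF3B3, another core subunit of SF3b, rose from 436 ± 13.7 to 763 ± 19.2 CPM (log2 fold change 0.81, standard error 0.04). SNRPA1 (0.66), SF3A2 (0.55), HTATSF1 (0.55), SNRPB2 (0.37) and SF3B2 (0.34) rose as well. The 3 that fell were DDX46, an RNA helicase of the early spliceosome, from 234 ± 11.5 to 104 ± 1.93 CPM (-1.16, limma adjusted p = 1.16e-10), SF1, the branch point binding protein (-0.39), and the helicase DDX42 (-0.20). The list's call was lost without DMSO replicate 3 (camera adjusted p = 0.0567).

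Among genes of other RNA-binding proteins, those of the hnRNP family mostly fell. Of 20 hnRNP genes 13 were listed, 2 of which rose and 11 of which fell, with a median of -0.29 (camera adjusted p = 0.0331, and adjusted p = 0.577 with an estimated correlation). HNRNPH1 fell from 655 ± 52.2 to 455 ± 4.49 CPM (log2 fold change -0.52) and HNRNPDL from 405 ± 15.5 to 287 ± 1.08 CPM (-0.50), while HNRNPR (0.32) and PTBP1 (0.21) rose. Of 20 SR protein and SR kinase genes 10 were listed, 4 of which rose, among them the kinase SRPK2 (0.32), and 6 of which fell, among them SRSF6 (-0.34), and the list did not pass the list test (median -0.17, mean -0.01, camera adjusted p = 0.834). Of 16 genes of nonsense-mediated decay and the exon junction complex 7 were listed, and 6 of them rose, among them CASC3 (0.41) and UPF1 (0.32), while SMG6 (-0.33) fell (camera adjusted p = 0.0911).

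Cell division genes fell. All 21 listed genes of the 24 on the mitosis list fell, with a median log2 fold change of -0.49 (camera adjusted p = 3.57e-06, and adjusted p = 0.113 with an estimated correlation). BUB1B, a spindle checkpoint kinase, went from 181 ± 5.28 to 102 ± 0.504 CPM (-0.83, standard error 0.04), and TOP2A, the topoisomerase that untangles chromosomes, from 895 ± 39.2 to 534 ± 17.8 CPM (-0.74, standard error 0.04). AURKB (-0.67), CENPE (-0.67), PLK1 (-0.49), CCNB1 (-0.41) and CDK1 (-0.37) fell too. Of the 24 DNA replication and E2F genes 15 were listed, of which 14 fell and 1, RFC4 (0.15), rose (median -0.33, camera adjusted p = 0.00138, and adjusted p = 0.315 with an estimated correlation). The rise of RFC4 did not pass under median-of-ratios scaling (0.07, limma adjusted p = 0.108), whose factors came only from genes selected as changed. CDC45, a part of the replicative helicase, fell from 124 ± 4.14 to 62.8 ± 1.46 CPM (-0.97), and RRM2, a ribonucleotide reductase subunit, from 451 ± 9.67 to 306 ± 4.01 CPM (-0.56).

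Homologous recombination and DNA damage response genes fell in 12 of 14 listed cases out of 22, with a median of -0.32 (camera adjusted p = 0.0263, and adjusted p = 0.475 with an estimated correlation). FANCI, of the Fanconi anemia pathway, fell from 388 ± 4.72 to 267 ± 3.41 CPM (-0.54) and CLSPN, an adaptor of the replication checkpoint, from 117 ± 5.6 to 81.1 ± 2.29 CPM (-0.52). The checkpoint kinase genes went apart, with CHEK1 (0.28) higher and CHEK2 (-0.55) and ATR (-0.48) lower. TOPBP1 (0.16) was the other gene of this list that rose, but it did not pass under median-of-ratios scaling (0.08, limma adjusted p = 0.0572).

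**Figure D2:**
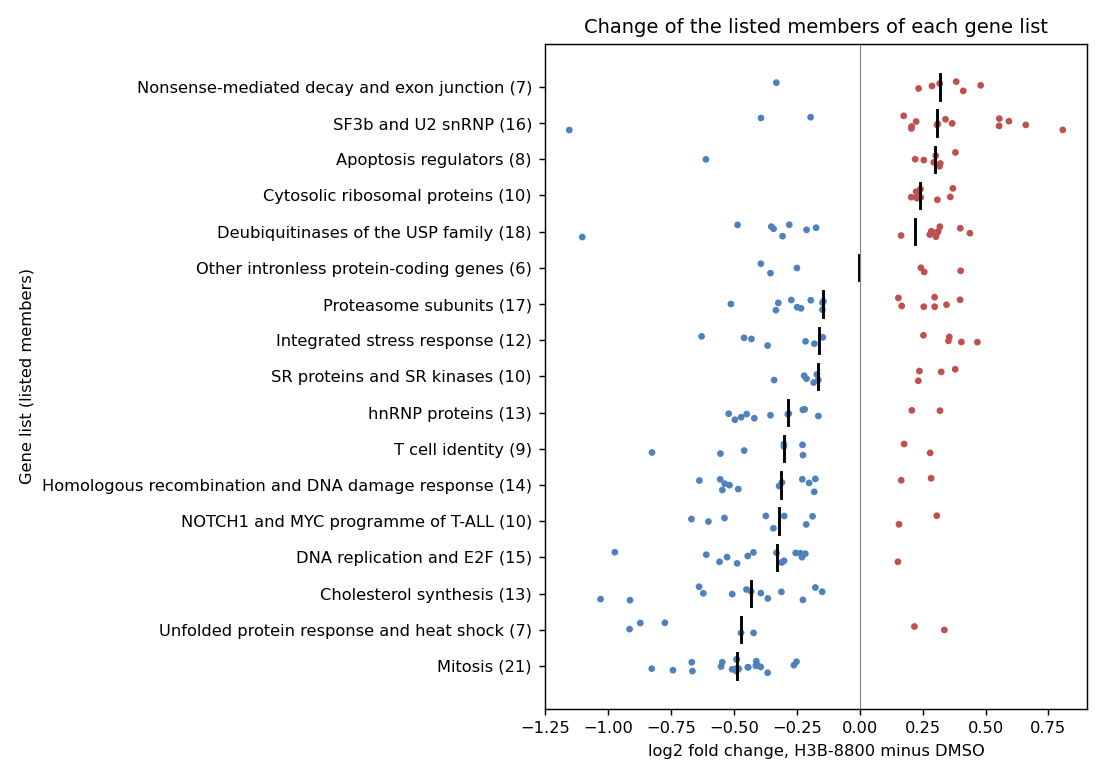
Each point is a listed gene placed by its log2 fold change of H3B-8800 minus DMSO, in rows for the 17 gene lists with at least 5 listed members (number in brackets), with risen genes in red, fallen genes in blue and a black bar at the list's median. The 21 mitosis genes and the 13 cholesterol synthesis genes all lie below 0, and the 10 ribosomal protein genes all lie above 0.

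Cholesterol synthesis genes also fell, in all 13 listed cases out of 22 (median -0.43, camera adjusted p = 0.000551, and adjusted p = 0.113 with an estimated correlation). FDPS, which makes farnesyl diphosphate, fell from 321 ± 5.68 to 157 ± 4.14 CPM (-1.03, standard error 0.04), and LSS, which closes the sterol ring, from 217 ± 12 to 115 ± 4.92 CPM (-0.91, standard error 0.05). The regulator SREBF2 (-0.43) fell less than FDPS and LSS, and about as much as the list's median. Cytosolic ribosomal protein genes rose in all 10 listed cases out of 30, by small amounts (median 0.24, or 0.16 under median-of-ratios scaling, camera adjusted p = 0.0283, and adjusted p = 0.518 with an estimated correlation). RPL4 rose from 1976 ± 74 to 2447 ± 87.9 CPM (0.31, standard error 0.05), and RPL5 (0.37) and RPS14 (0.24) rose as well. Ribosomal protein genes have many processed pseudogenes that can share their reads, so these values are uncertain.

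None of the lists of stress and protein turnover genes passed the list test. Of 20 unfolded protein response and heat shock genes 7 were listed, 5 of which fell, among them the endoplasmic reticulum chaperone HSPA5, from 409 ± 18.9 to 223 ± 5.28 CPM (-0.87), HSP90B1 (-0.78) and MANF (-0.92), while the cytosolic DNAJA1 (0.34) and HSPH1 (0.22) rose (median -0.47, camera adjusted p = 0.0919). Of 22 integrated stress response genes 12 were listed, 5 risen, among them TRIB3 (0.47), and 7 fallen, among them ATF5 (-0.63) (camera adjusted p = 0.814). Proteasome subunits split into 7 that rose and 10 that fell of 39 genes, with PSME1 (-0.51) lowest (camera adjusted p = 0.726). Deubiquitinases of the USP family split into 10 that rose and 8 that fell of 32 genes (camera adjusted p = 0.814), with a median of 0.22 and a mean of -0.01 that differ in sign. USP24 had the largest change of that family, from 169 ± 7.33 to 78.5 ± 9.13 CPM (-1.10, standard error 0.07).

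Of 20 genes of the NOTCH1 and MYC programme, which drives many T-ALL cells, 10 were listed, 8 of which fell and 2 of which rose (median -0.32, camera adjusted p = 0.0911). MYC fell from 314 ± 11.3 to 197 ± 0.632 CPM (-0.67, standard error 0.04), HES4 (-0.60) and NOTCH1 (-0.19) fell, and DTX1 (0.31) rose. Of 24 T cell identity genes 9 were listed, 7 fallen and 2 risen (median -0.30, camera adjusted p = 0.0919), among them CD1E, a CD1 family protein that acts inside the cell in lipid antigen handling, from 195 ± 6.34 to 110 ± 2.28 CPM (-0.83), and PTPRC (0.28). Of 26 apoptosis regulators 8 were listed (camera adjusted p = 0.129). The 7 that rose included CASP8 (0.30), an initiator caspase, and genes of proteins that block cell death, XIAP (0.32) and BCL2 (0.22). BIRC5, which also acts in mitosis, fell (-0.61).

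**Figure D3:**
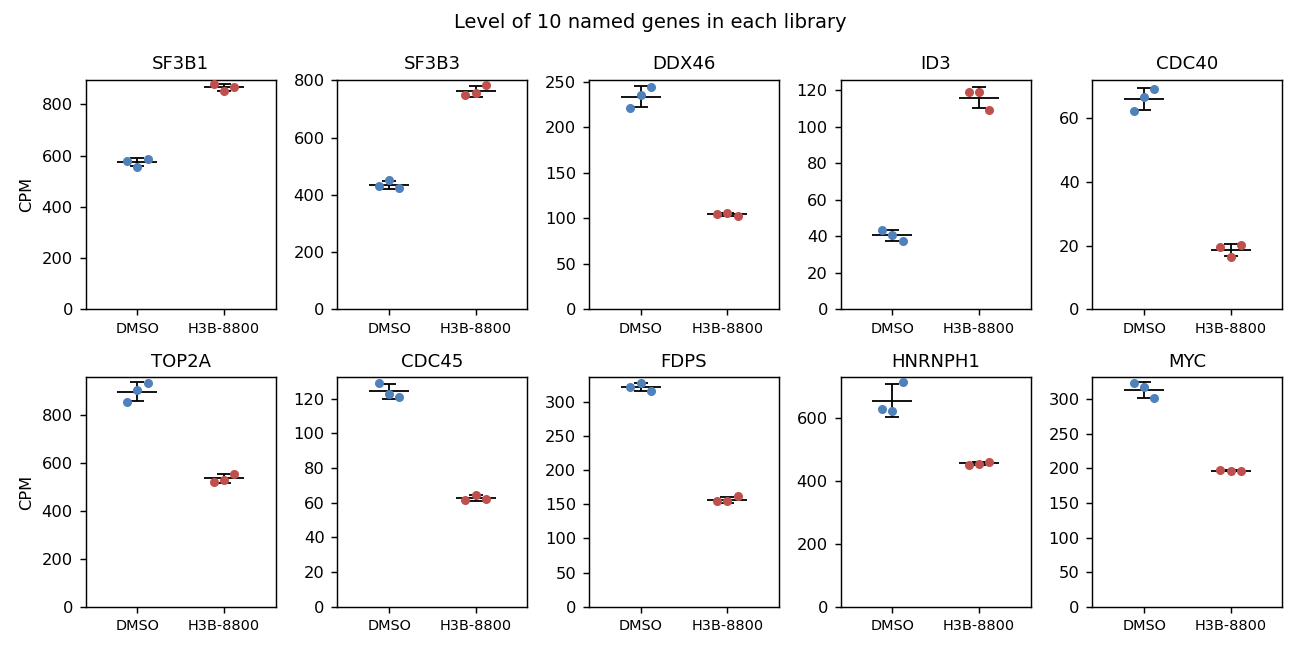
CPM of 10 named genes in each of the 6 libraries, with DMSO in blue and H3B-8800 in red, one point per library, a horizontal bar at the group mean and error bars of 1 SD (n = 3). In each panel the groups do not overlap, as for SF3B1 (574 against 867 CPM) and DDX46 (234 against 104 CPM).

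Some lists had few listed members and were not tested as lists. Of 24 interferon response genes 4 were listed, of which 3 rose, among them OAS2 (0.39) and BST2 (0.18), and OAS3 (-0.64) fell. BST2 did not pass under median-of-ratios scaling (0.10, limma adjusted p = 0.0548). TNFAIP3 (-0.58) was the 1 listed gene of T cell activation and immediate early response, and XPC (0.41) the 1 listed p53 target. Of 6 listed genes among 30 others without introns, 3 rose and 3 fell (camera adjusted p = 0.874), and the most abundant, HNRNPA0, fell (-0.36). Of the 13 mitochondrially encoded mRNAs MT-ND3 was the 1 listed, and although it passed the test (0.29, limma adjusted p = 0.00824), its groups overlapped, at 349 ± 33.3 and 428 ± 67.6 CPM, its change was 0.18 without H3B-8800 replicate 2, and its call was lost without DMSO replicate 2 (limma adjusted p = 0.0518). The snoRNA host genes are non-coding and could not be listed among protein-coding genes only. No replication-dependent histone gene was listed, which in libraries of poly-A RNA cannot be read as an effect of H3B-8800. No marker of monocytes, B cells, erythroid cells or epithelial cells and fibroblasts was listed either.

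Fold changes are on the log2(CPM + 1) scale and describe shares of each library, not RNA per cell. In each of the 17 lists the counts adjusted over the list alone equalled those over all listed genes, and the list test compared members only with other genes already selected as changed.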

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

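Scaling by median-of-ratios or upper-quartile factors on the listed genes, the test against a minimum fold, the adjustment over all genes the authors tested, and Fisher's exact test were chosen after seeing the data. Limma-voom had been planned for counts and was run on the whole reads worked out from the CPM values. All 2920 genes passed with the pseudocounts 0.1 and 5, with voom and with upper-quartile factors. Median-of-ratios factors shifted fold changes by -0.08 and left 2742 calls (1349 risen, 1393 fallen), so they ended only rises. Among these were the list members PHF5A, RFC4, TOPBP1, USP38, SHQ1, PSMB1, PSMD6, RUNX1 and BST2. The factors were computed only on genes selected as changed, so their shift depends on that selection. They cannot show whether these small rises are due to scaling. Leaving out 1 library gave 2908 to 2918 calls. An adjusted p under 0.01 gave 2896, and adjusting as if all genes the authors tested had been fitted gave 2894. None of these reversed a call, but the genes had been selected on the same libraries. With a log2 fold of at least 1, limma treat called 19 genes (1 risen, 18 fallen) and 44 genes passed in the authors' deposited table (1 risen, 43 fallen), since both demand a larger change.

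With an estimated correlation, camera called none of the 17 lists (2 at an unadjusted p under 0.05). The adjusted p was 0.113 for mitosis and for cholesterol synthesis, 0.315 for DNA replication, 0.475 for homologous recombination, 0.518 for SF3b and U2 snRNP and for ribosomal proteins, and 0.577 for hnRNP proteins; the cause was not tested. By Fisher's exact test of rises against falls the SF3b and U2 snRNP list had an adjusted p of 0.0559. Its median ranged from 0.29 to 0.344 with 1 library left out, and its camera adjusted p from 0.0272 to 0.0567, highest without DMSO replicate 3. Fry, which does not compare a list with other genes, also called nonsense-mediated decay (adjusted p = 0.000921), NOTCH1 and MYC (0.00193), T cell identity (0.00023), apoptosis (0.00242) and unfolded protein response (0.000782). Every listed member had already been selected as changed on these libraries. A list whose members mostly share a direction thus passes fry readily, and these calls add no independent evidence. Of 519 values of named genes under alternatives 518 stayed past the test in the same direction, and MT-ND3 missed it without DMSO replicate 2 (adjusted p = 0.0518).

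The submitters' design text speaks of matched pairs, but no label ties a replicate number to a shared day or culture. Same-numbered libraries deviated together with correlations of 0.07, 0.43 and -0.07 across genes, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries. The replicate block called 2920 genes, a count that cannot show its effect since every gene passed without it, and changed no list call. The limma adjusted p of BUB1B was 8.14e-16 with the block and 8.82e-10 without it. Variation shared by replicate number therefore stays open. The other tests planned for counts, and size factors over all genes, were not run, as the table holds CPM for listed genes; filters on low values removed no gene and test nothing. Counting error at 50 CPM was 2.55% to 2.87%, and genes the authors did not list have no value here.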

Other observations

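The tests of added gene groups, symbol groups, library scaling, the authors' listing rule and intron number were chosen after the results had been seen. Some gene groups outside the fixed lists also moved one way. All 8 such groups were put together from values of these libraries, so their tests are not independent evidence. All 13 listed glycolysis genes fell (median log2 fold change -0.34, camera adjusted p = 0.00149, and adjusted p = 0.464 with an estimated correlation), from ENO2 (-0.66) and GPI (-0.59) to GAPDH (-0.41) and HK1 (-0.16). All 8 listed fatty acid synthesis genes fell (median -0.51, camera adjusted p = 0.00149, and adjusted p = 0.364 with an estimated correlation), led by ACACA, the acetyl-CoA carboxylase of the first committed step (-1.43), the citrate carrier SLC25A1 (-1.12) and FASN (-0.81). All 9 listed genes of tubulins and their folding factors fell (median -0.44, camera adjusted p = 0.00149, and adjusted p = 0.364 with an estimated correlation), among them TUBA1B (-0.78) and TUBB (-0.71), which have close copies that could share their reads. The 6 listed GIMAP and GBP GTPase genes rose, with GIMAP7 at 0.83 and GIMAP4 at 0.65 (median 0.63, camera adjusted p = 0.00268, and adjusted p = 0.242 with an estimated correlation).

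The other groups gave no call. All 5 listed genes of the CCT chaperonin rose (median 0.26, camera adjusted p = 0.0599, and 0.032 without DMSO replicate 2, the 1 library whose omission brought a call). Aminoacyl-tRNA synthetase genes went both ways, with RARS at 0.58 and VARS at -0.64, as did those of translation initiation factor 3, with EIF3E at 0.45 and EIF3K at -0.28, and of mitochondrial ribosomal proteins, with MRPL2 at 0.64 and MRPS5 at -0.62. Of 39 groups formed from the letters that open a gene symbol, 1 differed from the rest in its split of rises and falls: all 18 listed RPL genes rose (Fisher's exact test, adjusted p = 0.000378). Of the 15 listed genes whose symbol opens with RPS, 12 rose and 3 fell (adjusted p = 0.183), and those that fell, RPS6KA3 (-0.27), RPS6KA4 (-0.26) and RPS6KB2 (-0.32), code for S6 kinases. Across the 2893 annotated genes, which are not independent replicates, the change had a Spearman rank correlation of -0.215 with transcript GC content (permutation p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.0004 over 4 properties), with median GC of 50.28% in fallen and 45.34% in risen genes. The rank correlation was -0.062 with the number of introns (adjusted permutation p = 0.0026), 0.044 with median intron length over 2870 genes (adjusted permutation p = 0.0224) and 0.021 with transcript length (adjusted permutation p = 0.2596). The share of fallen genes did not follow intron number in one direction: it was 60.9% of 23 genes without introns, 48.2% of 450 with 1 to 4, 40.6% of 858 with 5 to 9, 48.6% of 642 with 10 to 14, 49.2% of 622 with 15 to 24 and 61.4% of 298 with at least 25. Falls of at least 1 were seen in 1 of the 23 genes without introns and 7 of the 450 with 1 to 4. They were seen in 5 of the 858 with 5 to 9 and 8 of the 642 with 10 to 14. With 15 to 24 introns there were 10 of 622, and with at least 25 there were 7 of 298. Differences between these shares were not tested.

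Falls reached further than rises: the 1st percentile of fallen genes lay at -1.25 and the 99th percentile of risen genes at 0.75. The distance from the median was 1.94 times as long for falls (bootstrap interval 1.6 to 2.59), and 2.12 times after a fit on GC content and transcript length (1.70 to 2.57). A shift shared by a fixed set of rises and falls would leave these distances as they are. The genes were listed and split into rises and falls after scaling, however, so an effect of scaling through that selection was not tested. The CPM limit of the listing rule applied to the higher group for rises and falls alike. Among genes with at least 100 CPM in the higher group, 95% of changes of at least 1 were falls (19 of 20, exact interval 75.1% to 99.9%). These 20 are a part of the changes of that size already counted, so they cannot show whether the rule shaped the split. Among the 1491 genes with at most 10 introns, the median, the ratio was still 1.86 (interval 1.42 to 2.85), which argues against many introns as the whole cause, while a part stays open, since the median intron number of falls of at least 1 and of other falls differed by 0 with an interval of -2 to 7. A hypothesis left open is that reduced splicing may lower some transcripts strongly; splice junctions were not analysed here.

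Mitosis genes fell together, with a median of -0.49. Random lists matched on the change predicted from GC content, transcript length and introns had medians between -0.24 and 0.27 in the middle 95% of 10000 draws, and the list's median lay at percentile 0.00 of them. A linear fit on these properties explained 4.6% of the variance of the change, so matching on it held the random lists only loosely. The fall went beyond what this fit predicts. Effects of another shape were not tested, and the share of fallen genes did not follow intron number in one direction. The random lists were drawn gene by gene, however, and camera did not call the list with an estimated correlation (adjusted p = 0.113). A smaller share of dividing cells is a candidate explanation that was not tested.

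SF3b and U2 snRNP genes rose together, with a median of 0.31 against 0.16 over all listed genes. The difference was 0.14 (bootstrap interval 0.03 to 0.39), but it cannot weigh scaling as a cause. No listed change was smaller than 0.14 in absolute size in the authors' fit. A list of mostly risen genes therefore tends to lie above 0.16 whatever the scaling, and the median of all risen genes was 0.28. The list's median lay at percentile 99.83 of lists matched on GC content, length and introns. Those lists were drawn gene by gene, and the fit used for matching explained only 4.6% of the variance. A response of these genes to inhibition of their own complex may be one explanation, but the list's call rests on DMSO replicate 3 (camera adjusted p = 0.0567 without it) and on the preset correlation (adjusted p = 0.518 with an estimated one), and DDX46 went the other way (-1.16).

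Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, called 2920 genes and the highest of the others called 0 in limma (at most 9 genes at an unadjusted p under 0.05). With 10 splits a share under 0.05 cannot be reached, and the listed genes had been chosen on the real split.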
